A study of Mus musculus with 23 samples.

How the data were processed

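RNA was sequenced from 23 libraries of B-lineage cells sorted by flow cytometry from the bone marrow of C57BL/6 mice carrying an hCD25-lambda5 and a Rag1-GFP reporter. Per the labels, the 7 gates were pro-B1, pro-B2, pre-B1, pre-B2, pre-B3, Imm-B and Mat-B, with 3 libraries each except pre-B1 and Mat-B, which had 4. Mice were 8 weeks old, except for 3 libraries at 9 weeks. Per the labels' protocols, total RNA was isolated with the RNeasy Micro kit and libraries were made with the NuGEN Ovation RNA-Seq System and Ovation Ultralow V2 kits. Replicates were numbered as in the sample titles, with 0 where a title had no number. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries, part of which may be technical.

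Per the submitters' processing notes, the tools used were FastQC, HISAT and DESeq with the mm10 genome build. Versions, the read counter and the gene annotation are not given in the sources used here. The deposited values are a normalized signal per gene symbol, which the authors gave for the same 24062 symbols in each library. In each library 100% of these values were whole multiples of the value of 1 read, within 0.001 reads, so that they equal read counts divided by a size factor per library, and the counts of reads were recovered from the deposited signal. Recovered reads per library ran from 0.634 to 12.1 M (1 M is 1e6 reads) with a median of 4.31 M. A count of 3 reads, used as the floor for a gene with no reads, corresponded to 0.651 to 19.5 deposited units per library. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. The 45S pre-ribosomal RNA Rn45s took 3.12 to 13.4% of the deposited values of a library. Mitochondrially encoded genes and immunoglobulin gene segments other than Igll1 and its relatives were not among the symbols and are not analysed here. The extent to which reads were counted by strand is not given in the sources used here.

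Values were tested as log2(deposited value + 1). Genes with a value of at least 10 in at least 3 libraries were kept, which left 11815 genes. All 23 libraries entered 1 fit with 1 mean per gate in limma 3.58.1 (lmFit, then eBayes with an intensity trend) under R 4.3.3. Benjamini-Hochberg adjustment was made within a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were the 6 steps from pro-B1 to Mat-B, pre-B2 against pro-B1 (both gates of small cells), the difference between the big-against-small contrasts of the pro-B and the pre-B gates, and a moderated F test over the 7 gates. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. For genes without reads in 1 gate a lower bound is given against 3 reads summed over that gate. For genes with 1 to 3 reads a ratio with a 95% counting interval is given. It sets the mean of the higher gate against the reads of the lower gate, pooled over the depth of its libraries. Deeper libraries thus weigh more, and the ratio can differ from that of the printed means. Means are given ± SD and log2 fold changes ± SE.

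Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. The lists were the gate genes, pre-B cell receptor and its signalling, V(D)J recombination, early progenitor genes, B-lineage transcription factors, mature B cell surface genes, MHC class II presentation, DNA replication, mitosis, cell cycle inhibitors and quiescence, IL-7 receptor signalling, Myc and ribosome biogenesis, glycolysis, oxidative phosphorylation, NF-kB genes, immediate early genes, homing and adhesion, BCL2 family, immunoglobulin constant regions, interferon response, sex-linked transcripts, heat shock and RNA quality, and markers of T cells, NK cells, neutrophils and granulocytes, monocytes and macrophages, erythroid cells, plasmacytoid dendritic cells, plasma cells, megakaryocytes and platelets, basophils with mast cells and eosinophils, and stromal cells. Lists with at least 3 tested members entered camera. Beside the number of members called over all genes, the number adjusted over the list alone is given.

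The genes named in a comparison were the gate genes, up to 5 rises and 5 falls with the largest fold among called genes whose libraries did not overlap between the gates and whose higher mean was at least 50, and from each list up to 3 called members in each direction or, where none was called, up to 2 uncalled members. Most of these uncalled members are not printed. The groups, comparisons, tests, filter, lists, this rule and all alternatives other than those named next were fixed before the data were examined. Fits without the libraries labelled pre-B1 replicate 0, pre-B1 replicate 2 and pre-B2 replicate 0, whose gate genes differ from the other libraries of their gates, were chosen after the data were seen. Those fits were also run with the run tag, without Imm-B replicate 1, and with edgeR.

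The other settings were pseudocounts of 0.1 and 10, no filter, a filter of 50 in 3 libraries, TMM factors, quantile normalization, a common total per library, the gates of a comparison alone, the run tag of the deposited file with and without its sub-number as a covariate, the replicate number as a block, the libraries from mice of 8 weeks alone, library weights, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. The run tag has 3 levels. Xist was high in every library of one run and low in the other 2 runs, and the 9-week mice made up one of these 2, so that neither sex nor age can be told apart from run. In the run with high Xist, Ddx3y was 81.0 in pre-B1 replicate 2, 65.5 in Imm-B replicate 0, 13.4 and 8.78 in Mat-B replicates 2 and 1 and at most 1.55 in the others. In the other runs it was lowest in pre-B2 replicate 0 (20.8, with Xist at 18.4).

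The pipeline was tested on simulated counts with 200 changed genes for each of the 7 comparisons of 2 gates. The mitosis list was raised 4-fold besides. Its genes count among the calls below, but neither among the 200 nor among the false calls. At an assumed median dispersion of 0.3, 0 to 4.4% of the genes changed 2-fold, 15.2 to 28.8% of those changed 4-fold and 89.4 to 97% of those changed 16-fold were recovered, with 23 false among 609 calls. A second dispersion was estimated from all 23 libraries, pre-B1 replicates 0 and 2 and pre-B2 replicate 0 included. At this dispersion, with a median of 0.801, the shares were 0 to 1.5%, 0 to 7.6% and 25.8 to 50%, with 16 false among 242 calls, and 0 calls had the wrong direction in either setting. Changes of 2- to 4-fold were thus mostly below what the design could detect. Gene coordinates come from the GENCODE M21 annotation of GRCm38, matched by symbol. Vpreb1 and Vpreb2, Hba-a1 and Hba-a2, the Hbb genes, Bcl2a1b and Bcl2a1d, and Gapdh have near-identical copies or pseudogenes, and their values are uncertain for that reason.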

Results

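Gene expression was measured by RNA sequencing in 7 compartments of mouse bone marrow B-lineage cells, sorted by 2 reporters of stage (Rag1-GFP and an hCD25 reporter of Igll1, which encodes Lambda5), by cell size and by surface immunoglobulin. The pro-B1 (3 libraries) and pro-B2 (3) gates held small and big cells high in both reporters. The pre-B1 gate (4) held big cells intermediate in both reporters, the pre-B2 gate (3) small cells high for Rag and intermediate for Lambda5, and the pre-B3 gate (3) cells high for Rag and negative for Lambda5. The Imm-B (3) and Mat-B (4) gates held IgM-positive cells without and with IgD. Depth ran from 0.634 M reads (Mat-B replicate 3) to 12.1 M reads, and Spearman correlations between replicates ran from 0.621 to 0.915. In the Mat-B replicate 3 library, the gene Ralgps2 took 27.0% of the values.

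The gate genes themselves were read first, as the transcripts behind the reporters. Rag1 (GRCm38 chromosome 2, 101638282 to 101649501), which encodes a subunit of the V(D)J recombinase, had a mean deposited value of 3250 ± 346 (SD, n = 3) in pro-B1, 352 ± 88.2 (n = 3) in pro-B2 and 4510 ± 1070 (n = 3) in pre-B3. In pro-B2, gated as Rag-high, Rag1 was 453, 306 and 296, near the 288 and 406 of pre-B1 replicates 1 and 3, gated as Rag-intermediate. Igll1 (chromosome 16, 16860671 to 16863985), a component of the surrogate light chain, had 11630 ± 4560 in pro-B1 and 4472 ± 595 in pro-B2. In pre-B3, gated as Lambda5-negative, Igll1 had values of 143, 55.6 and 55.4 in the 3 libraries. Igll1 was 0, 89.8, 1.67 and 13 in the 4 Mat-B libraries. Cd19, required by the gates, had a value of at least 911 in all 23 libraries.

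In 3 libraries the gate genes departed from the other libraries of the same gate. In the library labelled pre-B1 replicate 0, Rag1 was 1.30 and Igll1 0.217, against 288 and 406 for Rag1 and 645 and 739 for Igll1 in pre-B1 replicates 1 and 3. The same library had a value of 5350 for Ms4a1, the gene of the mature B cell antigen CD20, where replicates 1 and 3 had 3.51 and 2.38. In the library labelled pre-B2 replicate 0, Rag1 was 0.612 and Igll1 11, against 1870 and 2504 for Rag1 and 230 and 345 for Igll1 in replicates 1 and 2, and Ms4a1 was 9031, against 117 and 332. The library labelled pre-B1 replicate 2 had 3160 for Rag1, 4260 for Igll1 and 4129 for Dntt, the terminal transferase of pro-B cells, where replicates 1 and 3 had 32.3 and 23.8 for Dntt. This library also held both the female transcript Xist (7424) and the Y-linked Ddx3y (81.0), as did Imm-B replicate 0 (13702 and 65.5) and, with less Ddx3y, Mat-B replicates 1 (14197 and 8.78) and 2 (13247 and 13.4). These 3 libraries stayed in every comparison, and a second fit without them, in which pre-B1 and pre-B2 had 2 libraries each, was chosen after the data were seen. Its values are given beside each count of genes and wherever it ended the call of a named gene or a list.

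**Figure D1:**
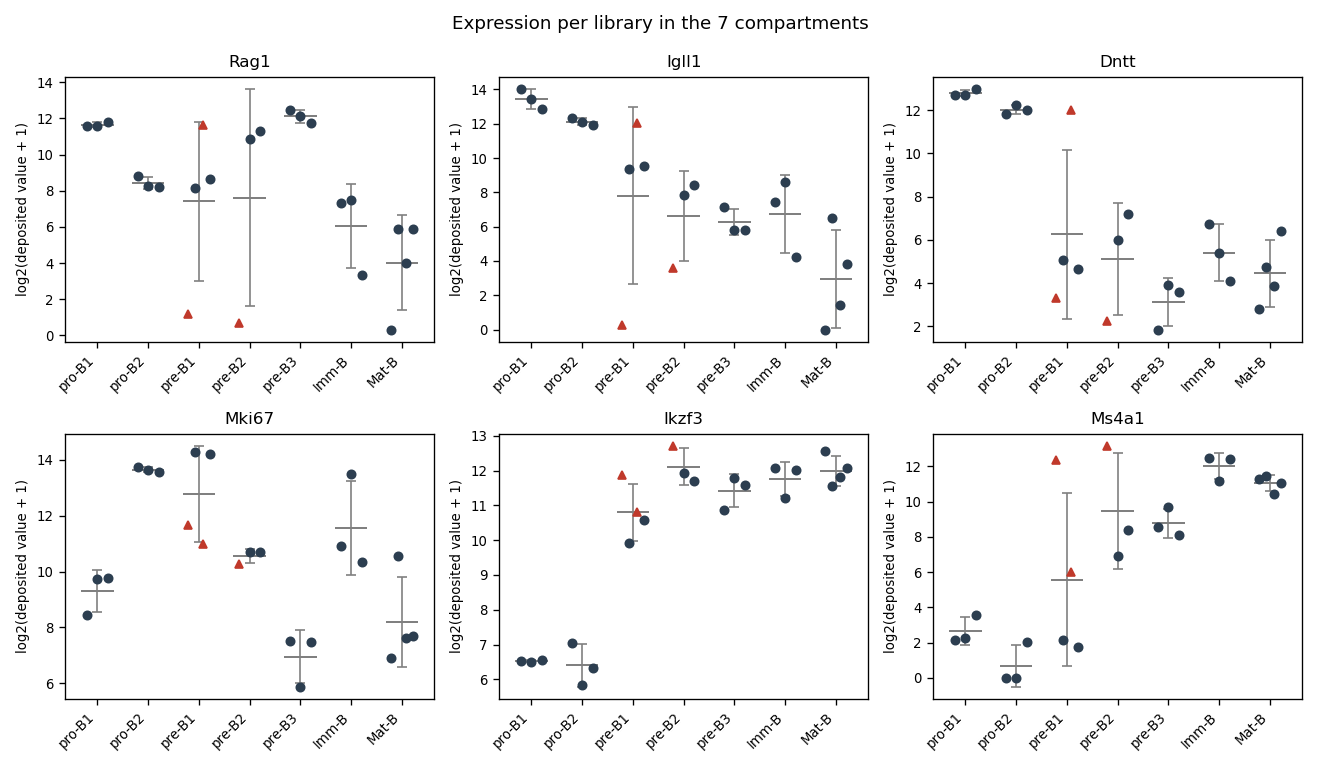
Deposited value per library on a log2(value + 1) axis for Rag1, Igll1, Dntt, Mki67, Ikzf3 and Ms4a1 in the 7 compartments, with a grey line at the mean, bars of 1 SD and red triangles for the 3 libraries whose gate genes departed from the others of their gates. The red triangles of pre-B1 replicate 0 and pre-B2 replicate 0 lie below their groups for Rag1 (1.30 and 0.612), and that of pre-B1 replicate 2 lies above its group (3160).

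Markers of other blood cells were read beside the gate genes. The neutrophil and granulocyte list summed to 2408 ± 3379 (SD, n = 3) in pro-B1, 299 in pro-B2, 1078 ± 1520 (n = 4) in pre-B1 and 2.01 in pre-B3. S100a8, an abundant neutrophil transcript, was 648, 0 and 2809 in the pro-B1 libraries and 1458 in the library labelled pre-B1 replicate 2. The NK cell list summed to 220 ± 110 in pro-B1 and 37.0 in pro-B2, and the T cell list to 301 ± 65.0 and 188. Klrb1c alone had a mean of 220 in pro-B1 and was the only NK cell gene to pass the filter. Lat had 195 of the T cell sum, and Cd3e, Cd3d, Cd3g, Cd4 and Cd8a did not pass the filter. These sums therefore do not show NK or T cells in pro-B1. Itgam, an integrin gene of myeloid and NK cells, was 1128, 548 and 331 in the pro-B1 libraries. Sums were 294 in pro-B1 and 210 in pro-B2 for monocyte and macrophage genes, 1465 and 719 for erythroid genes, 65.9 and 136 for plasmacytoid dendritic cell genes, and 1313 and 510 for plasma cell genes. In pro-B1, megakaryocyte and platelet genes summed to 3.81, basophil, mast cell and eosinophil genes to 21.9 and stromal genes to 1.45. Of the 12 immunoglobulin constant region genes none was among the symbols.

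The big pro-B2 cells were compared with the small pro-B1 cells to find what goes with cell size at the pro-B stage. Genes of cell division were far higher in pro-B2. Mki67, the proliferation marker, rose by 4.34 ± 0.81 on the log2 scale (SE, adjusted p = 0.00796), from 685 ± 294 to 12840 ± 747 (SD, n = 3 each). Ankle1 (chromosome 8, 71406010 to 71409904), an endonuclease gene, was 1040 times higher, with a counting interval of 356 to 5050. Kif18b and Nek2, a mitotic kinesin and kinase, were 541 (185 to 2620) and 1030 (185 to 40800) times higher. Kif14 rose by 8.11 ± 1.95, Bub1 of the spindle checkpoint by 7.93 ± 1.78, Nusap1 by 6.89 ± 1.36 and the spindle motor gene Kif11 by 7.34 ± 1.59. Of 30 measured members of the mitosis list 16 rose over all genes and 30 when adjusted over the list alone (camera adjusted p = 2.38e-32, and adjusted p = 0.0247 with an estimated correlation). Of 32 DNA replication genes 4 rose and 20 did so adjusted over the list alone (camera adjusted p = 8.37e-17, and adjusted p = 0.0265 with an estimated correlation). Among them Pcna, the sliding clamp, rose from 232 ± 119 to 2122 ± 210, Ccne1 by 6.30 ± 1.49 and Pola1 by 4.82 ± 1.21.

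Growth genes were also higher in pro-B2. Of 20 genes of Myc and ribosome biogenesis 2 rose, and 8 did so adjusted over the list alone (camera adjusted p = 5.4e-09, and adjusted p = 0.00195 with an estimated correlation). Ncl, which encodes nucleolin, rose from 1526 ± 164 to 4033 ± 85.7, and Polr1a of RNA polymerase I by 4.48 ± 1.08. Of 5 heat shock genes Hsp90aa1 rose, by 2.42 ± 0.63, and 4 rose adjusted over the list alone (camera adjusted p = 0.000217, and adjusted p = 0.0118 with an estimated correlation). Of 15 glycolysis genes Ldha rose, by 2.62 ± 0.70, and it was the only one adjusted over the list alone (camera adjusted p = 0.00392, lost at adjusted p = 0.0799 with an estimated correlation). The 22 oxidative phosphorylation genes held 0 called over all genes by limma and 1 adjusted over the list alone (camera up, adjusted p = 0.0204, lost at adjusted p = 0.359 with an estimated correlation). Flt3, a receptor gene of early progenitors, was 83.9 times higher (28.7 to 407).

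The lists of the pre-B cell receptor and of B-lineage transcription factors went the other way. Of 14 genes of the pre-B cell receptor and its signalling 2 fell and 6 did so adjusted over the list alone (camera adjusted p = 4.85e-05, and adjusted p = 0.0171 with an estimated correlation). Cd79b (chromosome 11, 106311341 to 106314762), which encodes Igβ, fell from 2365 ± 42.9 to 815 ± 168, and Cd79a from 3775 ± 661 to 1366 ± 279. Of 24 B-lineage transcription factors 3 fell and the same number did so adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.0367 with an estimated correlation), with changes of -2.04 ± 0.37 for Spib, -3.74 ± 0.78 for Bcl6 and -1.60 ± 0.43 for Foxo1. H2-Ob fell by 2.66 ± 0.60 among 14 MHC class II presentation genes, of which 4 fell adjusted over the list alone (camera adjusted p = 0.00563, lost at adjusted p = 0.292 with an estimated correlation). Cd38 fell by 2.41 ± 0.52 among 21 mature B cell surface genes, of which 4 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0303, lost at adjusted p = 0.436 with an estimated correlation). Txnip, a brake on glucose uptake, fell from 1372 ± 127 to 186 ± 110. The immediate early (16 genes), NF-kB (18) and interferon response (20) lists held 0 called genes in limma and were lower by camera, at adjusted p = 0.00392, 0.0204 and 0.00785. These calls were lost with an estimated correlation (adjusted p = 0.107, 0.359 and 0.316 with an estimated correlation).

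The genes with the largest falls included markers of other lineages. Itgam fell by 8.00 ± 1.65, from 669 ± 412 to 2.09 ± 2.82, and Klrb1c, which encodes the NK cell receptor NK1.1, by 6.76 ± 1.31. The NK cell sum of pro-B1 was almost all Klrb1c and is no separate evidence. Itgam did not follow the neutrophil transcript S100a8 over the pro-B1 libraries. Sertad4 fell by 6.71 ± 1.69, and Serpina3n and Ccdc33, without reads in pro-B2, were at least 199-fold and at least 252-fold lower. The gate genes Rag1 (-3.23 ± 1.99), Igll1 (-1.31 ± 1.80) and Cd19 (-0.95 ± 0.59) were not called (adjusted p = 0.482, 0.814 and 0.488, and camera adjusted p = 0.184 for these 3 gate genes as a list). In the fit without the 3 libraries the fall of Rag1 was called (adjusted p = 0.0403), and the gate genes were lower by camera (adjusted p = 0.0306, missed at adjusted p = 0.118 with an estimated correlation).

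Between pro-B2 and pro-B1, 255 genes were called, 151 higher and 104 lower. The count was 823 without the 3 libraries against their gates, 253 of them shared with the 255, and 275 of 389 genes were higher with a common total per library. It was 17 by edgeR and 521 by DESeq2. Leaving out 1 library gave 15 without pro-B2 replicate 1, 45 without pro-B2 replicate 0, 60 without pro-B1 replicate 0. It gave 106 without pro-B1 replicate 1, 123 without pro-B1 replicate 2 and 132 without pro-B2 replicate 2, against 593 without pre-B2 replicate 0. Of the 29 genes named as called here, 3 (Spib, Serpina3n and Ccdc33) kept the call whichever library was left out.

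The pre-B1 cells were compared with pro-B2, both gates of big cells, to read the passage from the pro-B to the pre-B stage. Ikzf3 (chromosome 11, 98464902 to 98546031), which encodes Aiolos, rose by 4.39 ± 0.42 (adjusted p = 1.14e-07), from 89.0 ± 39.0 (n = 3) to 2017 ± 1220 (n = 4). Cd2, a surface adhesion receptor gene, rose from 0.589 to 160 ± 78.2 and Polm, an end-joining polymerase gene, from 7.08 ± 7.83 to 557 ± 272. Adam19 rose by 6.56 ± 0.94 and Rasgrp1, a Ras activator gene, by 6.21 ± 0.87, and Itgb3 was 654 times higher (117 to 25800). Dntt fell by 5.76 ± 1.34, and in the fit without the 3 libraries it fell from 4157 ± 614 to 28.1 ± 6.01 (n = 2). Kit, the stem cell factor receptor gene, fell by 5.34 ± 1.26, Emp1 by 6.30 ± 1.23, Atp8b4 by 4.84 ± 1.11 and Clgn by 4.75 ± 1.01, and Bok was 675 times lower (121 to 26600). The gate genes Rag1 (-1.02 ± 1.86), Igll1 (-4.32 ± 1.69) and Cd19 (0.37 ± 0.55) were not called (adjusted p = 0.976, 0.46 and 0.963). Of 14 early progenitor genes 1 fell over all genes, and 4 adjusted over the list alone (camera adjusted p = 0.00517, lost at adjusted p = 0.19 with an estimated correlation).

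Genes of later B cells were higher in pre-B1. Of 21 mature B cell surface genes 3 rose and 11 did so adjusted over the list alone (camera adjusted p = 4.01e-15, and adjusted p = 0.0176 with an estimated correlation), with Cd38 up by 3.55 ± 0.49, Cd72 by 2.46 ± 0.48 and Ly6d by 4.15 ± 0.94. The list's mean log2 value was 8.98 in the library labelled pre-B1 replicate 0 and 5.06 to 6.05 in the other 3, and in the fit without the 3 libraries 2 of its genes rose and 4 did so adjusted over the list alone (camera adjusted p = 2.73e-06, and adjusted p = 0.0189 with an estimated correlation). Of 14 MHC class II genes 2 rose, H2-Aa by 5.04 ± 0.93 and Cd74 by 5.70 ± 1.14, and 10 did so adjusted over the list alone (camera adjusted p = 6.03e-14, and adjusted p = 0.00425 with an estimated correlation). In the fit without the 3 libraries 5 MHC class II genes were called (camera adjusted p = 3.98e-09), and the rise of Ly6d was no longer called (adjusted p = 0.338). Of 24 B-lineage transcription factors 2 rose, Ikzf3 and Spib (by 2.99 ± 0.35), and 6 did so adjusted over the list alone (camera adjusted p = 9.28e-06, and adjusted p = 0.00199 with an estimated correlation). With these libraries left out Bach2, a repressor of plasma cell fate, rose by 1.80 ± 0.30 and Bcl11a fell by 2.15 ± 0.46.

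Signalling genes of the pre-B cell receptor were among the rises. Cd79b rose by 1.66 ± 0.30, the kinase genes Syk by 1.90 ± 0.37 and Lyn by 1.78 ± 0.34, the 3 of 14 measured members called over all genes (camera adjusted p = 0.038, lost at adjusted p = 0.162 with an estimated correlation and at 0.591 without the 3 libraries). Of 16 genes of cell cycle inhibition and quiescence 2 rose, Klf2 by 5.61 ± 0.89 and Btg1 by 1.77 ± 0.39, and 4 did so adjusted over the list alone (camera adjusted p = 0.000422, and adjusted p = 0.0178 with an estimated correlation). Zfp36, an mRNA decay factor gene, rose by 2.06 ± 0.42 among 16 immediate early genes (camera adjusted p = 0.000627, lost at adjusted p = 0.0698 with an estimated correlation and at 0.189 without the 3 libraries). The NF-kB list held 0 genes called by limma over all genes and 5 higher adjusted over the list alone (camera adjusted p = 6.58e-05, lost at adjusted p = 0.138 with an estimated correlation). When the 3 libraries were left out 1 NF-kB gene was higher adjusted over the list alone and the median log2 change of the list was -0.14 (camera adjusted p = 0.591). Homing and adhesion genes were higher by camera (adjusted p = 0.0238, lost at adjusted p = 0.103 with an estimated correlation and at 0.116 without the 3 libraries). The Myc and ribosome biogenesis list was lower, with 1 gene adjusted over the list alone and 6 of them without the 3 libraries (camera adjusted p = 6.94e-08 and 4.75e-09, and adjusted p = 0.00199 with an estimated correlation). Heat shock genes were lower with all libraries (camera adjusted p = 0.000482, and adjusted p = 0.0111 with an estimated correlation), a call lost at adjusted p = 0.116 without the 3 libraries. Glycolysis genes were lower too (camera adjusted p = 0.00307, lost at adjusted p = 0.0768 with an estimated correlation and at 0.0699 without the 3 libraries).

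Between pre-B1 and pro-B2, 68 genes were called, 58 higher and 10 lower. There were 75 without the 3 libraries, 41 of them shared. There were 64 by edgeR and 214 by DESeq2, 5 in a fit of these gates alone, 33 without pro-B2 replicate 1 and 124 without pre-B2 replicate 0. The calls of Itgb3, Cd79b, Btg1 and Zfp36 were lost without the 3 libraries (adjusted p = 0.0515, 0.0515, 0.237 and 0.139). The mitosis and DNA replication lists were lower by camera with all libraries (adjusted p = 1.09e-05 and 0.000482, lost at adjusted p = 0.303 and 0.276 with an estimated correlation) and turned higher, uncalled, without the 3 libraries (adjusted p = 0.337 and 0.591). Mki67 was 19910 and 18700 in pre-B1 replicates 1 and 3, and 3279 and 2008 in the libraries labelled pre-B1 replicates 0 and 2. Of the 24 genes named as called, 11 kept the call whichever library was left out, Ikzf3, Cd2, Polm, Spib, Cd38 and Klf2 among them. Bok was not tested without a pro-B2 library, as it fell under the filter there.

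**Figure D2:**
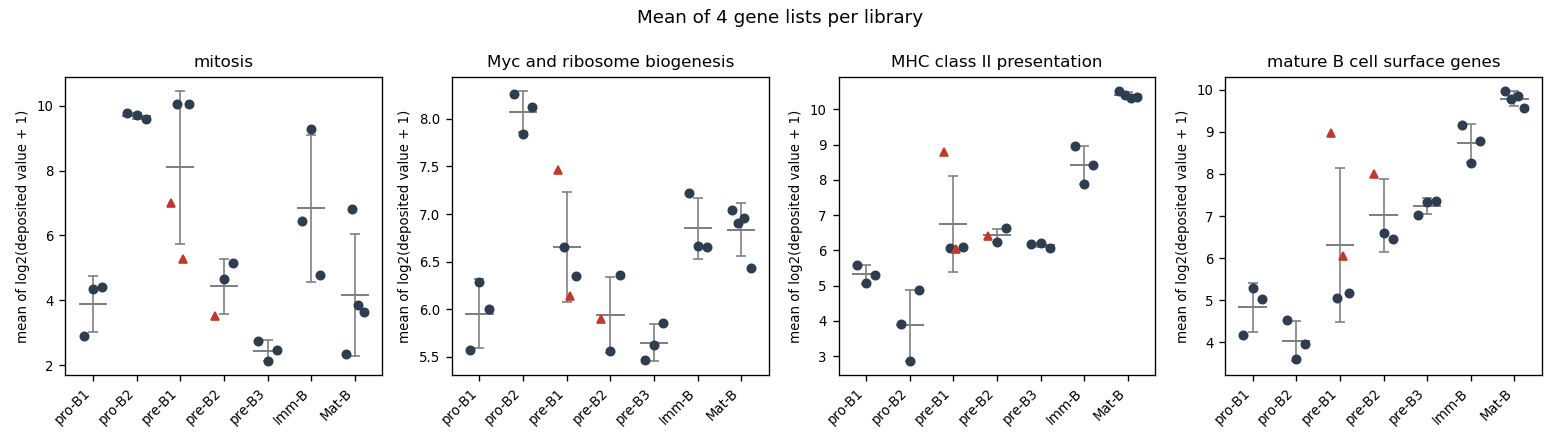
Mean of log2(deposited value + 1) over the members of the mitosis, Myc and ribosome biogenesis, MHC class II presentation and mature B cell surface lists, per library in the 7 compartments, with a grey line at the mean, bars of 1 SD and red triangles for the 3 libraries against their gates. In pre-B1 the MHC class II mean of replicate 0 (8.79) lies above those of the other 3 libraries (6.05 to 6.09).

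The small pre-B2 cells were compared with the big pre-B1 cells, the change of size at the pre-B stage. The pre-B2 gate was also high for Rag where the pre-B1 gate was intermediate, so size and Rag level cannot be told apart here. Dnajc7 (chromosome 11, 100582818 to 100620168), a co-chaperone gene, rose by 2.24 ± 0.43 (adjusted p = 0.0322), from 848 ± 212 (n = 4) to 3998 ± 1040 (n = 3). E2f3, a factor of the G1 to S transition, fell by 5.44 ± 1.08, from 234 ± 131 to 6.99 ± 8.82, Zdhhc18 by 5.08 ± 0.88 and Trim59 by 4.63 ± 0.93. Zfp827, with 1 read in pre-B2, was 373 times lower (66.9 to 14700), and Fhl3, with none, at least 88.8-fold lower. Among the gate genes Rag1 (0.20 ± 1.86), Igll1 (-1.18 ± 1.69) and Cd19 (1.34 ± 0.55) were uncalled (adjusted p = 0.97, 0.757 and 0.285). Leaving aside the 3 libraries against their gates, Rag1 was 288 and 406 in pre-B1 and 1870 and 2504 in pre-B2. Igll1 was 645 and 739 in pre-B1 and 230 and 345 in pre-B2. Of 30 mitosis genes 0 were called over all genes by limma and 21 were lower adjusted over the list alone (camera adjusted p = 2.31e-11, lost at adjusted p = 0.264 with an estimated correlation). The DNA replication list held 0 and 15 of 32 (camera adjusted p = 1.74e-08, lost at adjusted p = 0.264 with an estimated correlation). Mature B cell surface genes (adjusted p = 0.000123), the pre-B cell receptor list (0.000768), NF-kB genes (0.000768), immediate early genes (0.00984) and erythroid markers (0.00769) were higher by camera with 0 genes called. These calls were lost with an estimated correlation (adjusted p = 0.264, 0.0846, 0.264, 0.264 and 0.359 with an estimated correlation). B-lineage transcription factors were higher at adjusted p = 0.00222 (adjusted p = 0.0484 with an estimated correlation), with 1 higher and 1 lower adjusted over the list alone.

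In the fit without the 3 libraries, with 2 libraries in each gate, the same comparison called 101 genes. Top2a (chromosome 11, 98992943 to 99024189), which encodes topoisomerase IIα, fell by 5.91 ± 1.22 (adjusted p = 0.0202), from 6375 ± 752 to 155 ± 163, and Kif4 by 8.58 ± 1.77, Ttk by 7.36 ± 1.60, Ube2c by 7.22 ± 1.78 and the histone mRNA binding protein gene Slbp by 3.00 ± 0.67. Of 30 mitosis genes 8 fell, and 27 did so adjusted over the list alone (camera adjusted p = 4.74e-29, and adjusted p = 0.0237 with an estimated correlation). Of 32 DNA replication genes the numbers were 2 and 17 (camera adjusted p = 4.86e-18, and adjusted p = 0.0144 with an estimated correlation). Btg1, an antiproliferative gene, rose from 1231 ± 166 to 5993 ± 1180, Ms4a1 from 2.95 to 225 ± 152, and Bcl3, an NF-kB cofactor gene, by 7.29 ± 1.45. Of the mature B cell surface genes 3 rose and 9 did so adjusted over the list alone (camera adjusted p = 1.57e-08, and adjusted p = 0.0144 with an estimated correlation).

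With all libraries 8 genes were called between pre-B2 and pre-B1, 1 higher and 7 lower, against 1699 at an unadjusted p under 0.05, 3 genes by edgeR and 656 by DESeq2. The 101 genes without the 3 libraries share 6 with these 8. The count was 275 without pre-B2 replicate 2, 141 without pre-B2 replicate 1, 42 without pre-B1 replicate 2. It was 21 without pre-B3 replicate 0, 15 without pre-B1 replicate 0, 2 without pre-B1 replicate 3 and 1 without pre-B1 replicate 1. It was 5 without pro-B1 replicate 1, any of the 3 pro-B2 or the 3 Imm-B libraries, pre-B2 replicate 0 or Mat-B replicate 2. The median log2 change of all genes was -0.59 as deposited and 0.03 after quantile normalization, which called 1 gene. None of 16 called with a common total rose. Of the 6 genes named here Zfp827 alone kept the call whichever library was left out. The calls of Fhl3 and Zdhhc18 were lost without the 3 libraries (adjusted p = 0.129 and 0.0767).

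Both gates of small cells were also compared directly, pre-B2 against pro-B1. Ikzf3 rose by 5.58 ± 0.45 (adjusted p = 3.73e-09), from 91.4 ± 1.11 to 4627 ± 1780 (n = 3 each). Rasgrp1 was 1560 times higher (534 to 7570) and Cd2 775 times (214 to 6400). Btla, an inhibitory receptor gene, rose by 8.12 ± 1.44, Rnase6 by 8.00 ± 1.24 and Myl4 by 7.97 ± 1.23. Igll1 fell by 6.81 ± 1.80, from 11630 ± 4560 to 195 ± 170, beside the surrogate light chain genes Vpreb1 (-8.55 ± 1.89) and Vpreb2 (-7.80 ± 1.66), whose reads cannot be assigned safely between near-identical copies. Rag1 (-4.04 ± 1.99) and Cd19 (0.76 ± 0.59) were not called (adjusted p = 0.25 and 0.494). Rag1 was 0.612 in the library labelled pre-B2 replicate 0 and 1870 and 2504 in replicates 1 and 2. Dntt fell by 7.67 ± 1.43, from 7123 ± 775 to 70.1 ± 71.1. Arpp21 (chromosome 9, 112065091 to 112235938), a gene that hosts a microRNA, was 3100 times lower (1060 to 15000), and Mmrn1 and Parvb, without reads in pre-B2, at least 1250-fold and at least 874-fold lower. Erg, a factor of early progenitors, fell by 8.60 ± 1.79 and Atp2b4 by 8.55 ± 1.53.

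Mature surface genes were higher in pre-B2 than in pro-B1. Of 21 mature B cell surface genes 8 rose, over all genes as adjusted over the list alone (camera adjusted p = 7.46e-10, lost at adjusted p = 0.179 with an estimated correlation). When the 3 libraries were left out the numbers were 8 and 11 (camera adjusted p = 1.01e-08, and adjusted p = 0.0211 with an estimated correlation). Ly6d rose from 26.6 ± 22.7 to 2358 ± 1160, the inhibitory receptor gene Cd22 by 4.85 ± 0.85 and the chemokine receptor gene Ccr7 by 5.45 ± 0.995. Of 14 MHC class II genes 3 rose, Cd74 by 6.39 ± 1.22, H2-Aa by 3.83 ± 0.998 and H2-Eb1, which was 221 times higher (39.7 to 8730). Of these 14, 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00523, lost at adjusted p = 0.461 with an estimated correlation). Of 24 B-lineage transcription factors 6 rose and 1 fell (camera adjusted p = 0.00797, lost at adjusted p = 0.0837 with an estimated correlation). Ikzf1, which encodes Ikaros, rose by 1.93 ± 0.35 and Spib by 1.91 ± 0.37, and Lef1, a Wnt pathway factor, fell from 6485 ± 1480 to 230 ± 186. Of 18 NF-kB genes 2 rose, Bcl3 by 6.38 ± 1.49 and Nfkbia by 2.98 ± 0.88 (camera adjusted p = 0.00458, lost at adjusted p = 0.461 with an estimated correlation). Btg1 rose by 1.91 ± 0.41, Klf2 by 4.09 ± 0.95 and Zfp36 by 1.74 ± 0.45.

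The lists of the pre-B cell receptor and V(D)J recombination had calls in each direction. The pre-B cell receptor list had 2 rises, Lyn (1.75 ± 0.37) and Cd79b (1.06 ± 0.32), and 3 falls (camera adjusted p = 0.633), and V(D)J recombination 1 rise, Polm (6.34 ± 1.02), and 1 fall. The early progenitor list had 3 falls, with Kit 825 times lower (148 to 32600) and Egfl7 at least 225-fold lower, and 5 adjusted over the list alone (camera adjusted p = 0.067). Jak3, a kinase of the IL-7 receptor, fell from 343 ± 175 to 1.46 ± 0.264 and Jak1 by 1.61 ± 0.48. Among interferon response genes Ifit2 was 218 times (74.5 to 1060) and Ifi44 512 times (142 to 4230) lower, and 7 of 20 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.067). Myc fell by 4.17 ± 1.15, Polr1a rose by 5.11 ± 1.08, and Hk1, a hexokinase gene, fell by 4.61 ± 1.37. Of homing genes Itga4 fell by 1.36 ± 0.35 and Gpr183 fell by 4.46 ± 1.34. The mitosis list was higher by camera with 0 of 30 called by limma (adjusted p = 0.031, lost at adjusted p = 0.706 with an estimated correlation). Lat of the T cell list and Klrb1c of the NK cell list, without reads in pre-B2, were at least 310-fold and at least 350-fold lower. Cox6a2, on the plasmacytoid dendritic cell list, was 809 times higher (224 to 6680). It was 1239 in the library labelled pre-B2 replicate 0 and 120 and 22.5 in replicates 1 and 2, and its call was lost without replicate 0.

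Between pre-B2 and pro-B1, 633 genes were called, 163 higher and 470 lower, and after quantile normalization 222 of 516 were higher. The median log2 change of all genes was -0.52 as deposited and 0.06 after quantile normalization. There were 447 without the 3 libraries, 375 of them shared, 220 by edgeR, 1016 by DESeq2 and 1 in a fit of these gates alone. Leaving out 1 library gave 337 without pre-B2 replicate 0, 363 without pro-B1 replicate 0, 394 without pro-B1 replicate 1, 1056 without pre-B2 replicate 1 and 1107 without pre-B2 replicate 2. Without the 3 libraries the calls of Cd79b, Jak1, Hk1, Gpr183 and Cox6a2 were lost (adjusted p = 0.0669, 0.214, 0.316, 0.153 and 0.0757). Of the 46 genes named as called 31 kept the call whichever library was left out.

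The pre-B3 cells were compared with pre-B2, where the Lambda5 reporter is lost. Zfp827 (chromosome 8, 79028437 to 79193766), a zinc finger gene, was 460 times higher (82.5 to 18200). Zdhhc18 (chromosome 4, 133605299 to 133650154), a palmitoyltransferase gene, rose by 5.95 ± 0.94 from 2.56 ± 3.84 to 171 ± 106 (n = 3 each). Neo1, the netrin receptor gene neogenin, was 150 times higher (51.3 to 727). Igll1 differed by -0.35 (adjusted p = 0.987), Cd19 by -0.24 (adjusted p = 0.926) and Rag1 by 4.50 ± 1.99 (adjusted p = 0.372), with Rag1 near 0 in the library labelled pre-B2 replicate 0. Mki67 was 139 ± 70.4 in pre-B3 and 1519 ± 252 in pre-B2, a log2 difference of -3.60 ± 0.81 that missed the threshold (adjusted p = 0.127). The mitosis list was lower, with 0 of 30 genes called by limma and 1 adjusted over the list alone (camera adjusted p = 1.11e-06, lost at adjusted p = 0.862 with an estimated correlation). So was DNA replication with 0 and 3 of 32 (camera adjusted p = 0.00309, lost at adjusted p = 0.862 with an estimated correlation). These 3 called genes, all higher, stood against 1417 at an unadjusted p under 0.05, 1 gene by edgeR and 441 by DESeq2. The count was 99 without pre-B2 replicate 2, 97 without pre-B2 replicate 1, 7 without pro-B1 replicate 0, 5 without pre-B1 replicate 2 and 0 without pre-B3 replicate 2. Leaving out the 3 libraries gave 2, both shared, with Neo1 at an adjusted p = 0.0925. The calls of Zfp827 and Zdhhc18 were lost without pre-B3 replicate 2. The median log2 change of all genes was 0.10 as deposited and -0.03 after quantile normalization.

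The Imm-B cells, which carry surface IgM, were compared with pre-B3. The called gene was Mki67 (chromosome 7, 135689784 to 135716361), which rose by 4.62 ± 0.81 (adjusted p = 0.0466), from 139 ± 70.4 to 4893 ± 5710 (n = 3 each). It was 1918, 11474 and 1286 in the 3 Imm-B libraries. Of 30 mitosis genes 1 rose and 22 did so adjusted over the list alone (camera adjusted p = 1.88e-20). Of 32 DNA replication genes the numbers were 0 and 17 (camera adjusted p = 6.84e-14), and of 14 MHC class II genes 0 and 7 (camera adjusted p = 2.09e-05). These 3 calls were lost with an estimated correlation (adjusted p = 0.163 with an estimated correlation in each). The neutrophil and granulocyte list was higher (camera adjusted p = 0.0286, lost at adjusted p = 0.522 with an estimated correlation), from a sum of 2.01 in pre-B3 to 295 in Imm-B.

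In the fit without the 3 libraries, none of which belongs to these gates, the comparison of Imm-B with pre-B3 called 236 genes, 172 higher. The fold changes are those of the fit with all libraries, as the 3 libraries enter only through the shared spread and the filter. A fit of these gates alone, with fewer libraries to estimate the spread, called 1 gene. The genes named next thus rest on the spread of the other gates and on a choice made after the data were seen. Rag1 fell by 6.06 ± 0.97 (adjusted p = 0.00184), from 4510 ± 1070 to 115 ± 91.9 (n = 3 each). Bach2 (chromosome 4, 32238804 to 32586108) fell from 9311 ± 2020 to 3027 ± 1200, Ebf1, a factor of early B cell identity, from 3627 ± 590 to 1489 ± 60.0, and Cxcr4, the chemokine receptor gene of marrow retention, by 2.16 ± 0.42. Among MHC class II genes H2-Ab1 rose from 68.5 ± 45.2 to 973 ± 406, H2-DMa by 5.31 ± 1.02 and the transactivator gene Ciita by 5.55 ± 1.13. Of the 14 genes 6 rose, 7 adjusted over the list alone (camera adjusted p = 5.32e-06, missed at adjusted p = 0.0573 with an estimated correlation). Ms4a1 rose from 488 ± 292 to 4497 ± 1900, the follicular homing receptor gene Cxcr5 by 6.21 ± 1.202 and the BAFF receptor gene Tnfrsf13c by 1.73 ± 0.35. Of 21 mature B cell surface genes 4 rose and 1 fell (camera adjusted p = 0.00373, missed at adjusted p = 0.14 with an estimated correlation). In this fit 12 of 30 mitosis genes rose (camera adjusted p = 6.39e-20, missed at adjusted p = 0.119 with an estimated correlation). Of 32 DNA replication genes 10 rose (camera adjusted p = 9.18e-15, and adjusted p = 0.0452 with an estimated correlation), Prim1, Mcm4 and Mcm6 among them.

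With all libraries 1 gene was called between Imm-B and pre-B3 by limma, against 1191 at an unadjusted p under 0.05, 0 by edgeR and 349 by DESeq2. The count was also 1 in a fit of these gates alone. It was 236 without the 3 libraries, and 107 without these and Imm-B replicate 1. Leaving out 1 library gave 117 without pre-B2 replicate 0, 25 without pre-B2 replicate 1, 19 without pre-B2 replicate 2 or pre-B3 replicate 1, 17 without pre-B1 replicate 0. It gave 13 without pre-B1 replicate 2, 5 without pre-B3 replicate 2 and 4 without pro-B1 replicate 0. It gave 0 without pro-B1 replicates 1 or 2, any pro-B2 library, pre-B3 replicate 0, Imm-B replicates 0 or 1, or Mat-B replicates 2 or 3. The call of Mki67 was lost in these 10 fits and in the one without pre-B3 replicate 1. The median log2 change of all genes was 0.31 as deposited and 0.00 after quantile normalization, where 16 of 28 called genes were higher, against 20 of 26 with a common total. Rag1 (0.224), H2-Ab1 (0.0547), Bach2 (0.0791) and Cxcr5 (0.0814) had adjusted p above the threshold with all libraries, as had Igll1 (0.49 ± 1.80, adjusted p = 0.964) and Cd19 (-0.58 ± 0.59, adjusted p = 0.818).

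The Mat-B cells were compared with Imm-B, the step at which IgD appears. Homing genes were higher in Mat-B. Sell (chromosome 1, 164061982 to 164084181), which encodes L-selectin, rose by 4.68 ± 0.82 (adjusted p = 0.00231), from 218 ± 169 (n = 3) to 4206 ± 920 (n = 4). Ccr6, a chemokine receptor gene, rose from 2.82 ± 4.88 to 288 ± 120 and the integrin gene Itgb7 by 6.83 ± 1.15. Of the homing and adhesion list 3 genes rose, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.57e-05, and adjusted p = 0.011 with an estimated correlation). Rapgef4 (chromosome 2, 71981240 to 72257474), a Rap activator gene, was 718 times higher (199 to 5930), Nid1 511 times (91.7 to 20200), and Il9r, without reads in Imm-B, at least 146-fold.

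Antigen presentation genes were also higher. Of 14 MHC class II genes 2 rose, H2-Ab1 from 973 ± 406 to 7536 ± 1040 and H2-Ob from 904 ± 249 to 4724 ± 771, and 5 did so adjusted over the list alone (camera adjusted p = 4.93e-08, and adjusted p = 0.0416 with an estimated correlation). Of 21 mature B cell surface genes 2 rose, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00339, lost at adjusted p = 0.535 with an estimated correlation). The 2 were Sell and Itgb7, which also stand on the homing and adhesion list and are no separate evidence. Traf1 of the NF-kB list rose by 5.61 ± 1.35 and Pacsin1, on the plasmacytoid dendritic cell list, by 4.69 ± 1.06.

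Genes of earlier stages were among the falls in Mat-B. Myb (chromosome 10, 21124935 to 21160984), a progenitor transcription factor gene, fell from 1978 ± 702 to 170 ± 202, Cd93, the marker of transitional B cells, by 4.79 ± 0.94, and Vpreb3 from 1881 ± 84.8 to 450 ± 172. Of 24 B-lineage transcription factors 2 fell, among them Spib by 2.24 ± 0.35, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000676, and adjusted p = 0.011 with an estimated correlation). The early progenitor list had 2 falls, and 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0343, lost at adjusted p = 0.527 with an estimated correlation and at 0.0614 without the 3 libraries). Myb stands on both of these lists and counts in each. The pre-B cell receptor list had 1 fall (camera adjusted p = 0.0343, lost at adjusted p = 0.263 with an estimated correlation). Mki67 fell by 3.37 ± 0.76, 1 fall among 30 mitosis genes, with 3 adjusted over the list alone (camera adjusted p = 9.65e-12, lost at adjusted p = 0.263 with an estimated correlation). Its call was lost without Imm-B replicates 0 or 1 or Mat-B replicates 0, 2 or 3. The mean log2 value of the mitosis list was 9.27 in Imm-B replicate 1, against 6.45 and 4.78 in the other Imm-B libraries. It was 6.81 in Mat-B replicate 1 and 2.36, 3.87 and 3.63 in Mat-B replicates 0, 2 and 3. DNA replication held 0 genes called by limma and 2 lower adjusted over the list alone (camera adjusted p = 0.000113, lost at adjusted p = 0.477 with an estimated correlation). Ccnd2, which encodes cyclin D2, fell from 1104 ± 104 to 57.4 ± 57.0. Rapgefl1 fell by 7.33 ± 1.06, Gas7 fell by 6.69 ± 1.05, Slamf9 fell by 6.15 ± 1.40 and Col5a3 fell by 6.04 ± 1.42, and Acad8, without reads in Mat-B, was at least 153-fold lower.

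Between Mat-B and Imm-B, 91 genes were called, 40 higher and 51 lower, with 15 by edgeR and 169 by DESeq2. There were 208 without the 3 libraries, which held all 91. Leaving out 1 library gave 32 without Imm-B replicate 1, 33 without Imm-B replicate 0, 36 without Imm-B replicate 2, 39 without Mat-B replicate 0, 49 without Mat-B replicate 3, 55 without Mat-B replicate 2 and 153 without pre-B2 replicate 0. Of the 21 genes named as called, 10 kept the call whichever library was left out (Rapgef4, Ccr6, Itgb7, Nid1, Il9r, Rapgefl1, Gas7, Vpreb3, Myb and Spib). That of H2-Ab1 was lost in 13 of these fits. Rag1 (-2.02 ± 1.86), Igll1 (-3.83 ± 1.69) and Cd19 (0.58 ± 0.55) were uncalled (adjusted p = 0.878, 0.469 and 0.887).

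The change from small to big cells at the pro-B stage was compared with that at the pre-B stage, as the difference of both contrasts. Both pro-B gates were high for Rag, but the pre-B gates differed in Rag as well as in size. A difference of the contrasts may therefore go with either. Called genes were Srgap1 (-8.64 ± 1.64), Speer2 (-7.65 ± 1.497), Aldh1l1 (-7.02 ± 1.33), Zfp827 (-7.35 ± 1.42) and Ccdc33 (-7.69 ± 1.46), each at an adjusted p = 0.0438. Srgap1 falls outside the naming rule and was named after its values were seen. In pro-B1, pro-B2, pre-B1 and pre-B2 their means were 43.5, 0, 18.3 and 0 for Srgap1, 111, 0.161, 8.63 and 0 for Speer2 and 94.4, 0, 2.15 and 0 for Aldh1l1. They were 234, 77.9, 78.0 and 0.235 for Zfp827, and 127, 0, 5.30 and 0 for Ccdc33. Of the gate genes Rag1 (-3.03 ± 2.72), Igll1 (-2.49 ± 2.47) and Cd19 (0.38 ± 0.81) none was called (adjusted p = 0.725, 0.758 and 0.903). The Myc and ribosome biogenesis list was higher in the pro-B than in the pre-B contrast, with 0 genes over all genes in limma and 1 adjusted over the list alone (camera adjusted p = 8.79e-06, and adjusted p = 0.0163 with an estimated correlation). Mitosis (1.27e-07), DNA replication (0.0116) and heat shock (0.0107) genes were higher and neutrophil genes lower (0.0351) by camera. These calls were lost with an estimated correlation (adjusted p = 0.65, 0.723, 0.0722 and 0.723 with an estimated correlation). Without the 3 libraries the calls of mitosis, DNA replication and heat shock were lost as well (adjusted p = 0.193, 0.688 and 0.183), and that of the neutrophil genes was not (adjusted p = 0.0317). The count of 5 stood against 1141 genes at an unadjusted p under 0.05, 2 by edgeR and 161 by DESeq2, and was 0 without the 3 libraries. It was 0 in each fit without 1 of 18 libraries, 1 without pre-B2 replicate 1, 3 without pre-B1 replicate 2, 9 without pre-B1 replicate 0 and 13 without pre-B1 replicate 3. The median log2 difference of all genes was -0.55 as deposited and -0.01 after quantile normalization.

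Over the 7 compartments together 1746 genes varied by the F test, with 1421 by edgeR and 2445 by DESeq2, and 2656 without the 3 libraries. The BCL2 family (13 genes) passed camera in none of the comparisons with all libraries (lowest adjusted p = 0.104), nor did the plasma cell markers (0.111), the monocyte and macrophage markers (0.0508) or the sex-linked transcripts (0.12). Without the 3 libraries the monocyte and macrophage markers were lower by camera in the difference of the size contrasts (adjusted p = 0.0317, missed at adjusted p = 0.109 with an estimated correlation).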

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

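The tests of low depth, of RNA of male and female mice, of pre-B1 RNA, of cycling and of other splits were chosen after the results were seen, and those of mislabelling and of age or run before.

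Rag1 and Igll1 were near 0 in the libraries labelled pre-B1 replicate 0 and pre-B2 replicate 0, and in pre-B1 replicate 0 the mean log2 value of the MHC class II list was 8.79, against 6.05 to 6.09 in the other 3 libraries, a gap of 0.985 of the range. Low depth is argued against by the 3191 reads of Igll1 that the depth of pre-B1 replicate 0 would give at the level of replicates 1 and 3. Both libraries correlated best with Imm-B (mean Spearman 0.770 against 0.698 with the own gate, and 0.637 against 0.626), but the smaller excess of 0.011 leaves a wrong label open. Both came from 9-week mice of the same run, as did Mat-B replicate 0, whose deviation from its own group correlated with theirs at r = 0.16 across genes, which are not independent. With 1 library of that run per gate, the age, the run and a wrong label cannot be told apart, and a difference of the cells at 9 weeks also stays open.

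In the library labelled pre-B1 replicate 2, Rag1 was 3160 against 1.30 to 406 in the other pre-B1 libraries, a gap of 0.872 of the range, Dntt and Igll1 were at pro-B levels, and both Xist and Ddx3y were present. Its mean Spearman correlation was 0.836 with pro-B1 and 0.762 with pre-B1 replicates 1 and 3, an excess of 0.075, which a wrong label would give. The share of Xist (0.424 of its mean level in Xist-high libraries) and the median share of the Y-linked genes (0.524 of theirs, range 0.285 to 1.449) added to 0.948. A library of male and female RNA would give 1. Xist ran from 12953 to 27477 over the Xist-high libraries and was highest in pro-B1. Its share, and with it the sum, would be lower against pro-B1, so the closeness to 1 is loose. A wrong label and RNA of both sexes may hold together. Imm-B replicate 0 also held Xist (13702) and Ddx3y (65.5), as did Mat-B replicates 1 and 2 with less Ddx3y (8.78 and 13.4), and no biological explanation was tested.

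In Imm-B replicate 1, Mki67 was 11474, against 1918 and 1286 in the other Imm-B libraries. The sum of the surrogate light chain genes Igll1, Vpreb1 and Vpreb2 was 597, 2.194 times the higher of the other two (272 and 22.3), which is less than the spread between those, so cycling of Imm-B cells alone stays open. A share of pre-B1 RNA may also account for the pattern: the shares read from the mitosis genes (0.562), the surrogate light chain genes (0.553) and the mature and MHC class II genes (0.466) lay within 0.096 of the mitosis share. The Imm-B gate for surface IgM would remove pre-B1 cells.

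Of 68 tests of a library far from the other 3 of its gate 5 passed, where chance passes about 1 in 20. Beside those above, the monocyte and macrophage list had a mean log2 value of 1.65 in pre-B1 replicate 3, against 3.05 to 3.18 (gap 0.910 of the range). Igll1 was 89.8 in Mat-B replicate 1, against 0 to 13 (gap 0.855). The homing and adhesion list had a mean log2 value of 8.23 in Mat-B replicate 1, against 8.56 to 8.63 (gap 0.834).

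The contrast of big with small cells differed between the pro-B and the pre-B stage, by the test of the difference itself, for Srgap1 (-8.64), Ccdc33 (-7.69), Speer2 (-7.65), Zfp827 (-7.35) and Aldh1l1 (-7.02). None of these 5 was called without the 3 libraries against their gates, in limma. The pre-B gates of this contrast also differ in Rag, which the pro-B gates do not.

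Other splits of the libraries of a comparison were run in the same way. The real split gave the most genes for pre-B1 against pro-B2 (68 genes, highest other split 54 with pre-B1 replicate 2 moved to the pro-B2 side, and 1 of 35 splits as large, the real one), Mat-B against Imm-B (91, highest other 42, 1 of 35) and the F test (1746, highest other 84, 1 of 100). A test with 35 splits can give no share under 1 of 35, and the tests were not corrected for their number. Chance is thus less likely there but not excluded. Other splits were as large for pre-B2 against pre-B1 (8 genes, 7 of 35 splits as large, highest other 23 with pre-B1 replicates 1 and 3 and pre-B2 replicate 0 on one side). For the difference of the size contrasts 14 of 100 splits were as large (5 genes, highest other 557 with all pro-B2 libraries, pre-B1 replicates 1 and 3 and pro-B1 replicate 0 on one side). Those splits moved libraries freely among pro-B1, pro-B2, pre-B1 and pre-B2, so differences by size and stage enter them. They therefore cannot decide on chance for these 5 genes. In the split with 557, that side held the libraries with the highest mitosis list means, 9.60 to 10.06, beside pro-B1 replicate 0 at 2.90. The highest mean on the other side was 7.01, and the reason for that split was not tested. The splits were too few, 10 each, for pro-B2 against pro-B1 (255 genes, highest other 3, 1 split as large), pre-B2 against pro-B1 (633, highest other 1, 1 as large), Imm-B against pre-B3 (1, highest other 0, 1 as large) and pre-B3 against pre-B2 (3, 3 as large, highest other 36 with pre-B2 replicate 0 and pre-B3 replicates 0 and 2 together).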

How the results depend on the processing

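The fits without the 3 libraries against their gates (alone, with the run tag, without Imm-B replicate 1, and in edgeR) were chosen after the data were seen. Comparisons are written here as pro-B2/pro-B1, with the size difference for the difference of both size contrasts. The counts to set beside are 255 for pro-B2/pro-B1, 68 for pre-B1/pro-B2, 8 for pre-B2/pre-B1, 633 for pre-B2/pro-B1, 3 for pre-B3/pre-B2, 1 for Imm-B/pre-B3, 91 for Mat-B/Imm-B, 5 for the size difference and 1746 for the F test. Of the counts under another setting 200 stayed within 1.5 times these values and 177 did not. Of the values for the 134 named calls, 4697 kept the call and 911 lost it, and 0 changed direction. For the 59 list calls, 2214 kept the call, 199 lost it and 6 turned. Except where libraries or genes were removed, the cause was not tested.

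Counts outside that range follow by setting. A pseudocount of 0.1 gave 125 for pro-B2/pro-B1, 7 for Imm-B/pre-B3, 40 for Mat-B/Imm-B and 1 for the size difference, and one of 10 gave 590 for pro-B2/pro-B1, 27 for pre-B2/pre-B1, 25 for Imm-B/pre-B3, 141 for Mat-B/Imm-B and 24 for the size difference. No filter gave 4 for pre-B2/pre-B1, 7 for pre-B3/pre-B2, 4 for Imm-B/pre-B3, 55 for Mat-B/Imm-B and 25 for the size difference. A filter of 50 gave 13 for pre-B2/pre-B1 and 0 for Imm-B/pre-B3 and the size difference. Quantile normalization gave 673 for pro-B2/pro-B1, 142 for pre-B1/pro-B2, 1 for pre-B2/pre-B1, 1 for pre-B3/pre-B2, 28 for Imm-B/pre-B3, 163 for Mat-B/Imm-B and 0 for the size difference. A common total gave 389 for pro-B2/pro-B1, 16 for pre-B2/pre-B1, 26 for Imm-B/pre-B3 and 10 for the size difference, and TMM 0 for Imm-B/pre-B3. The gates of a comparison alone, with fewer libraries to estimate the spread, gave 430 for pro-B2/pro-B1, 5 for pre-B1/pro-B2, 1 for pre-B2/pro-B1, and 0 for pre-B2/pre-B1, pre-B3/pre-B2 and the size difference.

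The run tag as a covariate gave 442 for pro-B2/pro-B1, 19 for pre-B2/pre-B1, 54 for Imm-B/pre-B3 and 0 for the size difference. With its sub-number it gave 412 for pro-B2/pro-B1, 13 for pre-B2/pre-B1, 419 for pre-B2/pro-B1, 48 for Imm-B/pre-B3 and 14 for the size difference. Without the 9-week libraries there were 719 for pro-B2/pro-B1, 403 for pre-B2/pro-B1, 227 for Imm-B/pre-B3 and 0 for the size difference. Library weights gave 1252 for pro-B2/pro-B1, 439 for pre-B1/pro-B2, 615 for pre-B2/pre-B1, 5 for pre-B3/pre-B2, 212 for Imm-B/pre-B3, 279 for Mat-B/Imm-B, 27 for the size difference and 3920 for the F test.

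On the recovered reads, edgeR gave 17 for pro-B2/pro-B1, 3 for pre-B2/pre-B1, 220 for pre-B2/pro-B1, 1 for pre-B3/pre-B2, 0 for Imm-B/pre-B3, 15 for Mat-B/Imm-B and 2 for the size difference. DESeq2 gave 521 for pro-B2/pro-B1, 214 for pre-B1/pro-B2, 656 for pre-B2/pre-B1, 1016 for pre-B2/pro-B1, 441 for pre-B3/pre-B2, 349 for Imm-B/pre-B3, 169 for Mat-B/Imm-B and 161 for the size difference. Without the 3 libraries edgeR gave 499 for pro-B2/pro-B1, 34 for pre-B2/pre-B1, 179 for pre-B2/pro-B1, 246 for Imm-B/pre-B3 and 0 for pre-B3/pre-B2 and the size difference.

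Without the 3 libraries limma gave 823 for pro-B2/pro-B1, 101 for pre-B2/pre-B1, 236 for Imm-B/pre-B3, 208 for Mat-B/Imm-B, 0 for the size difference and 2656 for the F test. With the run tag as well it gave 863 for pro-B2/pro-B1, 121 for pre-B2/pre-B1, 266 for Imm-B/pre-B3 and 0 for the size difference. Without Imm-B replicate 1 as well it gave 816 for pro-B2/pro-B1, 111 for pre-B2/pre-B1, 107 for Imm-B/pre-B3, 0 for the size difference and 2629 for the F test. The lists that turned from lower to higher, uncalled, in pre-B1/pro-B2 were DNA replication (adjusted p = 0.591, 0.682 and 0.607 in these 3 fits) and mitosis (adjusted p = 0.337, 0.217 and 0.286).

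The replicate number as a block gave 3 for pre-B2/pre-B1, 27 for Imm-B/pre-B3 and 9 for the size difference. The labels do not say that the numbers pair the samples. The residuals of the 64 pairs of libraries with the same number had a median correlation of 0.03 (range -0.0461 to 0.423), with 8 pairs over 0.1, against 5 of 162 pairs with different numbers. Of the 23 libraries 16 correlated best with a library of their own number, a hint of pairing from the data for part of the libraries, and the block was kept as an alternative.

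Leaving out 1 library at a time gave 15 to 593 for pro-B2/pro-B1, 33 to 124 for pre-B1/pro-B2, 1 to 275 for pre-B2/pre-B1, 337 to 1107 for pre-B2/pro-B1, 0 to 99 for pre-B3/pre-B2, 0 to 117 for Imm-B/pre-B3, 32 to 153 for Mat-B/Imm-B, 0 to 13 for the size difference and 1331 to 2140 for the F test. Among the 134 named calls, edgeR lost 75, DESeq2 16, the gates of a comparison alone 94 and a pseudocount of 0.1 lost 38. Of the same 134, no filter lost 34, the 8-week libraries alone 22, the fit without the 3 libraries 17, the run tag 12 and the replicate block 9. No value was given for 9 of them by a filter of 50 and for 2 by DESeq2, nor for Bok without a pro-B2 library, Neo1 without a pre-B3 library and Aldh1l1 without a pro-B1 library. Among the 59 list calls, an estimated correlation lost 42, fry 35, the fit without the 3 libraries 10 and the run tag 4. The spread between libraries limits the counts: at most 28.8% of simulated 4-fold changes were recovered at the lower dispersion and 7.6% at the estimated one. The 3 libraries against their gates entered that estimate, so their differences count as spread in it. Depth was not varied in these simulations, and it sets the floor of 3 reads at 0.651 to 19.5 deposited units.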

Other observations

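The fit without the 3 libraries, used for the overlap of the size contrasts and for the lists, was chosen after the data were seen.

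Without the 3 libraries against their gates, the contrast of big with small cells could be read at both the pro-B and the pre-B stage, from libraries that the contrasts do not share. At the pre-B stage the gates differ in Rag as well as in size. Of the 452 genes higher in pro-B2 than in pro-B1 and the 67 higher in pre-B1 than in pre-B2, 55 were the same genes, where 2.60 would be shared by chance with independent genes, and of 371 and 34 lower genes 14 were shared, against 1.08. Both contrasts used the same estimate of spread per gene, so genes with a low spread are called more easily in both. The chance values do not allow for this. No gene was called in opposite directions in these limma contrasts. Across 11652 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.48 and a Spearman correlation of 0.39. With all libraries, where chance would give 0.0895 higher and 0.0088 lower genes, 0 were shared in either direction in limma, so the sharing could not be read there. The correlations were 0.26 and 0.20. Mitosis genes summed to 1541 ± 308 (SD, n = 3) in pro-B1 and 41640 ± 3633 (n = 3) in pro-B2.

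Several lists passed camera in the fit without the 3 libraries and not with all libraries. Interferon response genes were lower in pre-B1 than in pro-B2 (adjusted p = 0.0071) and in pre-B2 than in pro-B1 (0.00755), calls lost with an estimated correlation (adjusted p = 0.183 and 0.291 with an estimated correlation). Heat shock genes were lower in pre-B2 than in pre-B1 (adjusted p = 0.00288, and adjusted p = 0.0237 with an estimated correlation), as were glycolysis genes (adjusted p = 0.023, and adjusted p = 0.0473 with an estimated correlation). Cell cycle inhibitors and quiescence genes were higher there (adjusted p = 0.0159, and adjusted p = 0.0473 with an estimated correlation). Mature B cell surface genes were higher in pre-B3 than in pre-B2 (adjusted p = 0.00173, missed at adjusted p = 0.302 with an estimated correlation).

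Summed MHC class II values (mean ± SD) were 2235 ± 739 in pro-B1, 648 ± 100.4 in pro-B2, 7207 ± 10570 in pre-B1, 7794 ± 8939 in pre-B2, 3785 ± 1529 in pre-B3, 14830 ± 4131 in Imm-B and 55600 ± 6891 in Mat-B. Erythroid marker sums were 4130 ± 1293 in pre-B2, 2331 ± 2392 in pre-B3, 3383 ± 2512 in Imm-B and 719 ± 123 in pro-B2. The sum of plasmacytoid dendritic cell genes was 481 ± 659 in pre-B2, an SD above the mean, and 99.5 ± 95.9 in pre-B3, and stromal genes summed to 84.9 ± 66.3 in Mat-B.

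Within pro-B1, Xist was 27477 and 24763 in pro-B1 replicates 0 and 1, and 51.3 in replicate 2, where Ddx3y was 172. The library labelled pre-B2 replicate 0 had reads in 7603 genes, and Herc1 took 4.94% of its values.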
